A study of Homo sapiens with 2 samples.

How the data were processed

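Total RNA of U87 glioma cells was taken 48 h after lipid-mediated plasmid transfection and labelled with Cy3, per the labels' protocols. Each of the 2 samples, 1 control and 1 FOXP3, was hybridised to its own one-colour Agilent array. The deposited scanner files hold spot intensity on a linear scale. Per the file headers the processed signal intensity was background-subtracted and detrended within each array by Feature Extraction 10.7.3.1, while the submitters' processing notes name version 9.1. The same deposited files hold flags for background, saturation and outlier spots. The deposited value table holds log2 values, without a stated method. Its columns had medians of 5.897 each, their sorted values agreed within 0.001, and each had a Pearson r of 0.9999 with the log2 processed signal of its array, so the scale is log2 with no centring per gene, after quantile normalization. It was used as an alternative.

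In the main setting, the log2 processed signal of each spot was averaged per probe after control spots and outlier spots were left out, and the 75th percentile of each array was subtracted. Before scaling that percentile was 722.9 on the control array and 634.4 on the FOXP3 array. Of 41000 probes, 11 had outlier spots only on an array and were left out. Probe names were updated through a table of RefSeq genes of assembly GRCh38.p14, used for names only: 27286 probes matched by accession, 2382 by symbol and 454 by an older symbol, and 10867 were left without a gene. Coordinates are those of the file headers' build, hg19. A gene was represented by its brightest probe among those well above background on both arrays. A gene with no probe well above background on 1 array was given a bound: the bright array's scaled signal against the higher of the dim array's lowest signal well above background and the dim probe's own. Signal over background sets what could be measured: the lowest signal well above background was 8.60 on the control array and 8.97 on the FOXP3 array. Signals without background subtraction and the normexp correction both gave smaller bounds for FOXP3 and ARHGAP15 and fewer genes past 2-fold. The cause was not tested.

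With 1 array per group no test was possible. Differences were described by a fixed size of 2-fold. Each gene list was described by its median and that median's percentile among 10000 random lists of the same size, matched on mean signal in 20 bins. A list was singled out below percentile 2.5 or above 97.5, which chance gives for 5% of lists of randomly drawn genes, and needed 5 measured members. Of 37 lists fixed in advance, 2 are not reported here. The spread of a single-spot difference came from 216 detected probes printed in several spots.

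A rule for the genes to name was fixed before the data were examined, as were the lists and the first set of alternatives. The rule took FOXP3, ARHGAP15 and RAC1, then the 10 highest and 10 lowest symbol-named genes at or above the median signal that were at least 2-fold in the same direction under normexp and quantile normalization with all detected probes of the same sign; 4 lower genes qualified. It also took the 3 largest bounds in each direction, up to 4 members past 2-fold in each list, and the 2 members farthest in the direction of a singled-out list with fewer than 2 such members.

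Alternatives were normexp background correction with offset 50, quantile and cyclic loess normalization (limma 3.58.1 in R 4.3.3), scaling to the median of detected probes or to the spike-ins, mean signal without subtraction, the deposited value table, the mean over probes, a filter at the median signal, no background filter, outlier spots kept, fold sizes of 1.5 and 3, and unmatched random lists. Lists matched on signal and probe GC content, probes of at most 60% GC and protein-coding genes alone were chosen after seeing the data. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The functions were tested on simulated data for this comparison of 13738 genes: 100 of 100 genes set 2.5 higher or lower on the log2 scale and 99 of 100 set 1.5 higher or lower were recovered. In the same test 4.5% of 1000 random lists were singled out, and 0 of 13538 unchanged genes passed 2-fold. The simulated noise was independent for each probe, and all probes of a gene were shifted alike. On the real arrays the log2 differences of 2 probes of a gene had a Pearson r of only 0.25. The test thus checks the functions and does not show how often a 2-fold difference in the data is real.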

Results

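The data were gene expression profiles of U87 cells, an established human glioma cell line, collected 48 h after transfection with a control plasmid or with a plasmid for FOXP3, a forkhead transcription factor best known from regulatory T cells. One-colour Agilent arrays of 60-base probes were used, with 1 array in each group. No difference below has a replicate check, no p-value was computed, and each value describes these 2 arrays. The arrays came from different slides, so slide and group cannot be told apart. On the control array 66.5% of the 43376 non-control spots were well above background, and on the FOXP3 array 66.7%. No spot was saturated. The number of arrays limits the precision. With genes split by signal into 3 equal parts, the median spread of a single-spot log2 difference within these arrays was 0.15 (SD) for dim, 0.10 for middle and 0.09 for bright genes. That spread covers spot error and leaves out cultures, RNA and labelling.

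The first comparison asked whether the transfected gene and the genes in the title of the series, ARHGAP15 and RAC1, differed between the arrays. FOXP3 was not well above background on the control array, with a processed signal of 2.23, and reached 696.5 on the FOXP3 array, at least 92.3-fold higher. The FOXP3 bound was 12.4-fold after normexp background correction and 14.8-fold on signals without background subtraction. The single FOXP3 probe maps to chromosome X, 49109625 to 49110398 in hg19, a span longer than the probe, so it crosses an exon junction. ARHGAP15, a GTPase-activating protein that turns off the small GTPase RAC1, was dim on both arrays. Its 5′ probe (chromosome 2, 143913200 to 143959737) read 2.54 on the control array, not well above background, and 16 on the FOXP3 array, at least 2.12-fold higher. The bound for ARHGAP15 was under 2-fold in 5 of 7 other background and scaling settings, down to 1.35-fold on signals without background subtraction. These 5 are not separate checks. Normexp and unsubtracted signals both add more than 16 to a signal, which makes so dim a ratio smaller. The deposited value table nearly repeats quantile normalization. The 3′ probe of ARHGAP15 (chromosome 2, 144276907 to 144314009) read 5.24 on the control array and 3.60 on the FOXP3 array, well above background on neither, so the higher reading rests on 1 of 2 probes.

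RAC1, the GTPase that drives membrane ruffling and cell migration, was bright on both arrays and slightly lower on the FOXP3 array by all 3 of its probes. The brightest RAC1 probe (chromosome 7, 6426872 to 6431571) read 15467 on the control array and 11298 on the FOXP3 array, a scaled log2 difference of -0.27. The other RAC1 probes differed by -0.13 and -0.57 on the log2 scale, all under 2-fold. The probe at -0.57 (6443013 to 6443072) was printed in 10 spots, and the other 2 in 1 spot each. The probe at -0.13 (6426881 to 6431580) covers nearly the same span as the brightest, so these are not separate readings. The log2 differences of all genes had an SD of 0.34.

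**Figure D1:**
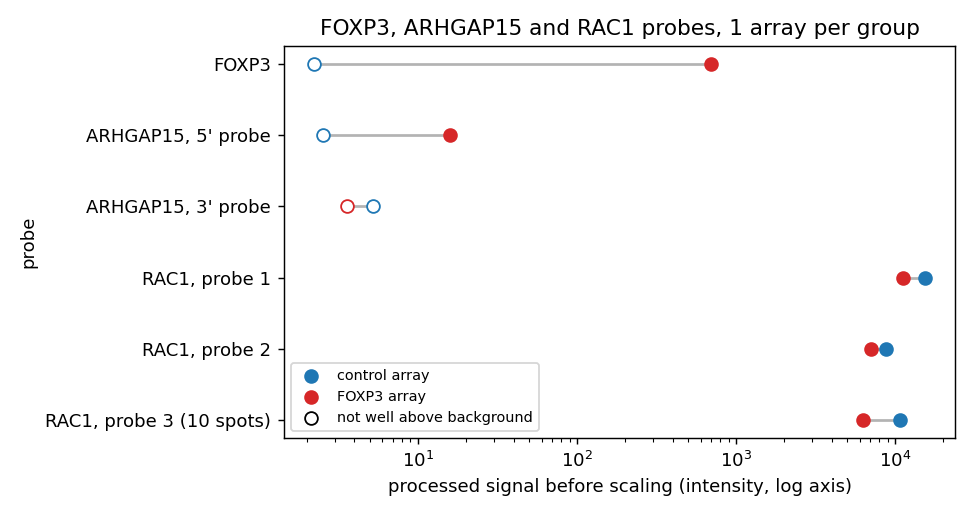
Processed signal (intensity, log axis) of each FOXP3, ARHGAP15 and RAC1 probe on the control array (blue) and the FOXP3 array (red), before scaling; open points were not well above background. The FOXP3 probe reads 2.23 on the control array and 696.5 on the FOXP3 array, while the ARHGAP15 probes stay at or below 16.

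The next comparison covered all named genes. Among 13738 genes well above background on both arrays, 231 were at least 2-fold higher on the FOXP3 array and 23 at least 2-fold lower. Of the higher genes, 171 lay below the median signal, and normexp background correction left 94 higher and 10 lower. Among the brighter higher genes, POU3F3, a transcription factor, differed by 1.998 on the log2 scale, SOX3, also a transcription factor, by 1.97 and CEBPA, a regulator of myeloid and fat cell differentiation, by 1.90. These 3 genes have 1 detected probe each, of at least 70% GC. At least 2-fold higher were 6.58% of detected probes above 60% and up to 70% GC, and 16.1% of those above 70%. SPPL2B, an intramembrane protease, differed by 2.05 at its brightest probe and by 0.14 at the lowest of its 2 probes, and VSIG10L by 1.74 and 0.04. RPLP0P2 and RPS10P7, pseudogenes of ribosomal proteins, differed by 1.87 and 1.85 and share sequence with their parent genes. NACA2 differed by 1.76, IFITM5 by 1.65 and MT1L, a metallothionein family member, by 1.55.

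The named lower genes were 4. SLC34A3, a kidney phosphate transporter, differed by -1.39, RAVER1, an RNA-binding protein, by -1.24 with its other probe at -0.60, NBPF10 by -1.24 and NEUROG3, a factor of endocrine cell development, by -1.03. The probe of SLC34A3 has 70% GC and that of RAVER1 78.3%, and 3.32% of detected probes above 70% GC were at least 2-fold lower against 0.33% of those above 60% and up to 70%. With probes of at most 60% GC, 15 genes in place of 23 were lower. All 3 probes of NBPF10, a member of a family of near-identical copies, were lower, from -1.35 to -0.87.

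**Figure D2:**
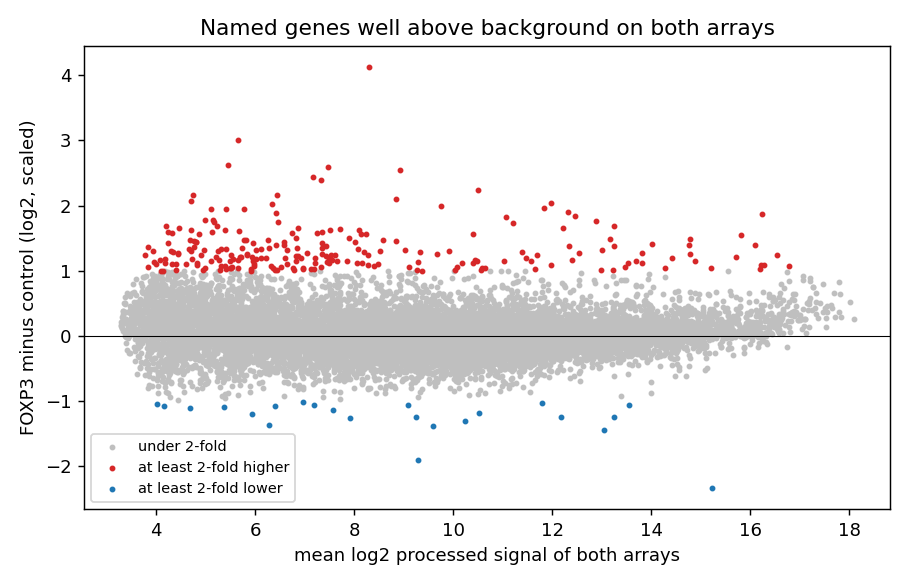
Scaled log2 difference, FOXP3 minus control, against the mean log2 processed signal for each of 13738 named genes. The 231 genes at least 2-fold higher are red and the 23 at least 2-fold lower are blue.

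A further set of genes was well above background on 1 array only, and each has only a bound. On the FOXP3 array alone there were 287 such genes, 80 of them at least 2-fold higher by the bound. On the control array alone there were 200, 8 of them at least 2-fold higher there. The 2 counts rest on unequal floors. The lowest signal well above background was 8.60 against a 75th percentile of 722.9 on the control array. On the FOXP3 array it was 8.97 against 634.4. A signal of 15.1 on the FOXP3 array alone could reach 2-fold, while 19.9 on the control array alone did not. The bound thus passes 2-fold more easily for the FOXP3 array, and 80 and 8 are not on equal terms. With a looser detection flag these counts of 80 and 8 became 391 and 146. DDX25, a testis RNA helicase, read 2.32 on the control array and 658.0 on the FOXP3 array, at least 87.2-fold higher. That value rests on 1 probe printed in 1 spot, with no second probe to check it. CCL21, a chemokine of lymphoid tissue, was at least 4.61-fold higher. In the other direction IP6K3 was at least 7.04-fold, VNN3P at least 5.30-fold and WDFY4 at least 3.53-fold higher on the control array.

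The signalling question was addressed with lists of genes fixed before the data were examined. None of the 20 measured Rac-directed GTPase-activating proteins differed by 2-fold, and their median log2 difference was -0.09, at the 7.57th percentile of random lists. ARHGAP15 and ARHGAP9 of that list were well above background on the FOXP3 array only, by at least 2.12-fold and 1.30-fold. Rac exchange factors (23 measured) had a median of -0.12 at percentile 3.64, and none of them differed by 2-fold at its brightest probe. DOCK3, named after its values were seen, differed by 0.11 at its brightest probe and by 1.13 at the other. ELMO1 of that list was well above background on the control array only, at least 1.18-fold higher there.

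Of the lists on invasion, extracellular matrix genes were lower as a group, with a median of -0.20 at percentile 0.02. FBN2 and FBN1, which encode fibrillins, differed by -0.69 and -0.47, while BGN, a small proteoglycan near the detection limit, was 1.30 higher. Integrins and focal adhesion genes had a median of -0.09 (percentile 2.67), epithelial-mesenchymal transition genes -0.09 (8.41) and matrix proteases and their inhibitors -0.04 (10.5). MMP16, a membrane-bound matrix protease, was the member past 2-fold, at -1.37. Its 3 probes ran from -1.37 to -0.34.

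Of 35 lists reported here, 5 lay above and 3 below the middle 95% of random lists, where chance gives 1.75 for genes drawn at random. Genes of 1 list can move together between any 2 cultures or slides, so a number above 1.75 is no evidence of a FOXP3 effect. Metallothioneins and zinc-response genes had the highest median, 0.59 (0.23 after quantile normalization), with 2 of 13 measured members at least 2-fold higher. MT1L differed by 1.55 and MT1G by 1.08, with the other MT1G probe at 0.26. The 11 measured metallothioneins were above 0, while the zinc transporters SLC30A1 and SLC39A10, named after their values were seen, differed by -0.45 and -0.71. Ribosomal protein genes had a median of 0.29 (percentile 99.9), but -0.06 after quantile normalization and in the deposited value table, where the median of all genes was also -0.06. RPS23 differed by 1.48, RPL14 by 1.40 and RPL7 by 1.25, with the other RPL7 probe at 0.63. The probes of RPL14 ran from -0.15 to 1.98, and it was at -0.46 after quantile normalization, where another of its probes was the brightest. Replication-dependent histone genes had a median of 0.24 (0.16 after quantile normalization), with H4C3 at 0.89 and H4C4 at 0.82. Metallothionein, ribosomal protein and histone genes are families of similar sequence whose probes can share targets.

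NRF2 and oxidative stress genes had a median of 0.17 (percentile 99.1), with ME1, which supplies NADPH, at 1.47 and GPX2 at 0.66, both dim. The NRF2 median was 0.06 after quantile normalization, and among genes at or above the median signal it lay at percentile 80.3, inside the random range. Apoptosis regulators had a median of 0.13 (percentile 98.9), but lay inside the random range with the mean over probes (0.08, percentile 93.6) and among genes at or above the median signal (0.07, percentile 86.8). HRK differed by 0.86 and CASP8, the initiator caspase of death receptors, by 0.78, but other probes of these genes differed by 0.00 and 0.07. G2/M genes were lower, with a median of -0.20 and 8 of 43 members above 0. KIF14 and CENPE, motor proteins of mitosis, differed by -0.92 and -0.80. Hypoxia genes had a median of -0.09 (percentile 1.02), with BNIP3L at -0.54 (its other probe at -0.09) and BHLHE40 at -0.48. That list lay inside the random range under 8 of 13 alternatives.

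**Figure D3:**
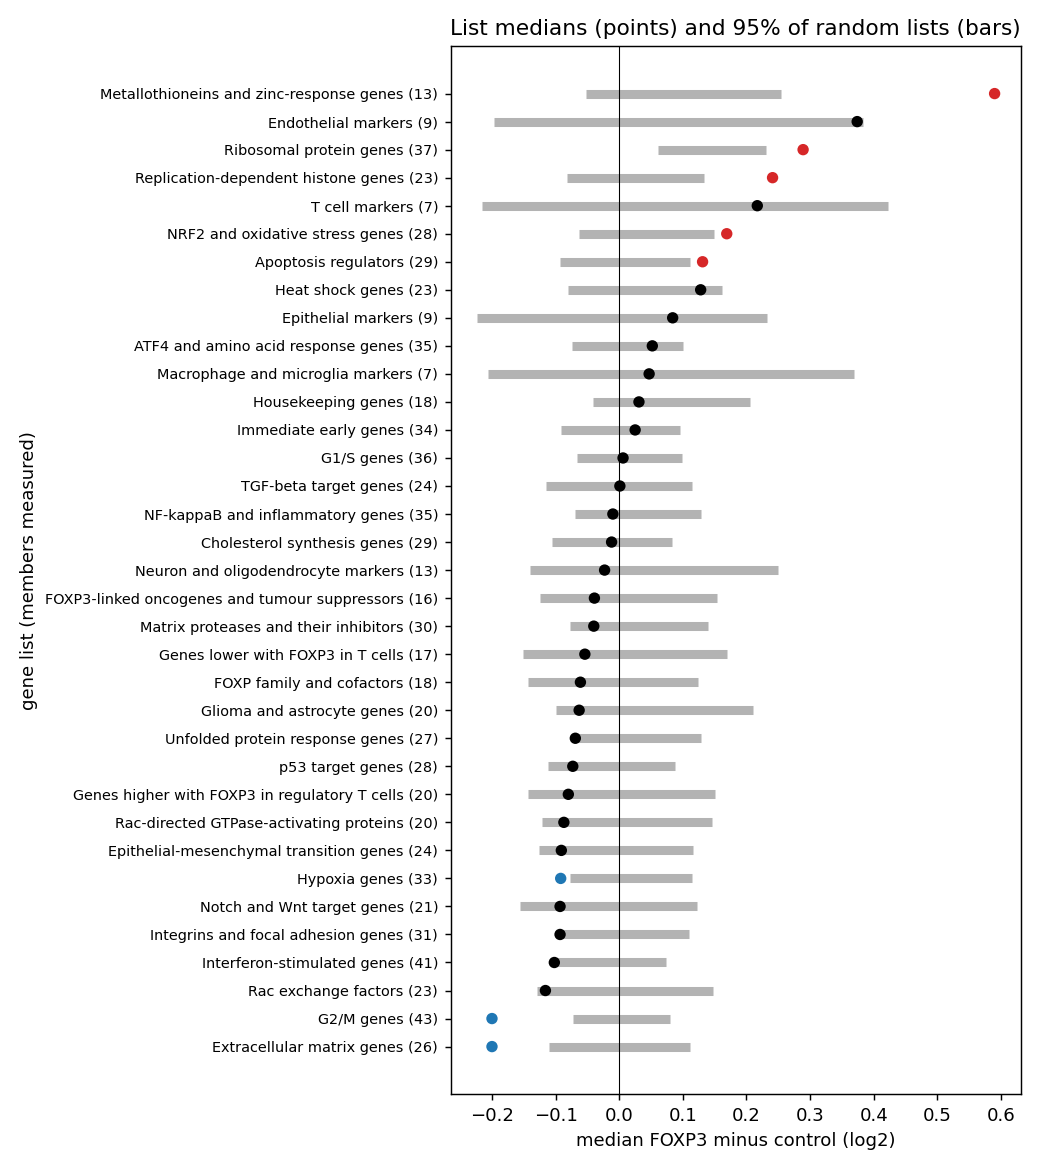
Median log2 difference, FOXP3 minus control, of each gene list (points) and the middle 95% of 10000 random lists matched on signal (bars), with the number of measured members. Red points are the 5 lists above that range and blue points the 3 below it; the ribosomal protein median, 0.29 here, is -0.06 after quantile normalization, like the median of all genes there.

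The lists built around FOXP3 lay inside the random range. Genes higher with FOXP3 in regulatory T cells had a median of -0.08 (percentile 14.1) over 20 of 32 members, and genes lower with FOXP3 in T cells -0.05 (23.9) over 17 of 29. The other 12 members of each list were not well above background on either array, among them IL2RA, CTLA4, ICOS, IL2 and IFNG, named after their values were seen, so the medians say nothing of them. FOXP3-linked oncogenes and tumour suppressors had a median of -0.04 (23.3), and the FOXP family and cofactors -0.06 (21.8). No member measured on both arrays differed by 2-fold in these 4 lists. In the FOXP family and cofactors, FOXP3 itself was well above background on the FOXP3 array only, and NFATC2 on the control array only, at least 2.13-fold higher there.

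The remaining lists also lay inside the random range. Interferon-stimulated genes had a median of -0.10 (percentile 3.16), p53 target genes -0.07 (12.1), unfolded protein response genes -0.07 (2.84) and NF-kappaB and inflammatory genes -0.01 (23.5). CXCL8, a neutrophil chemokine of the latter list, was 1.25 higher. Notch and Wnt target genes had a median of -0.09 (14.6), with NKD2 at 1.57. Glioma and astrocyte genes had a median of -0.06 (6.57), with the astrocyte filament gene GFAP at 1.11 and dim on both arrays. EFEMP1 of the matrix list, HEY2 of the Notch list and POU3F2 of the glioma list were well above background on the FOXP3 array only, by at least 1.34-fold, 1.96-fold and 1.68-fold, and BST2 of the interferon list on the control array only, by at least 1.27-fold. The medians were 0.01 for G1/S genes, 0.05 for ATF4 and amino acid response genes, 0.13 for heat shock genes, -0.01 for cholesterol synthesis genes, 0.03 for immediate early genes, 0.00 for TGF-beta target genes and 0.03 for housekeeping genes. Among markers of other cell types the medians were 0.22 for T cells, 0.05 for macrophages and microglia, 0.37 for endothelium, 0.08 for epithelium and -0.02 for neurons and oligodendrocytes. Between 7 and 13 of these markers were measured on both arrays per list, none past 2-fold. STMN2, a neuronal marker, and ESRP1, an epithelial marker, were well above background on the FOXP3 array only, by at least 3.42-fold and 2.18-fold. So were the T cell markers CD8A and CD3E, by at least 1.41-fold and 1.27-fold.

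Different probes of a gene often differed. Across 5552 genes with more than 1 detected probe, the log2 differences of the 2 brightest probes had a Pearson r of 0.25. Genes are not independent replicates. In 57 genes whose brightest probe was at least 2-fold higher, the second probe was above 0 in 37 and at least 2-fold higher in 3. In genes whose brightest probe differed less than 2-fold, the second was on the same side of 0 in 59.2%. In the 10 genes whose brightest probe was at least 2-fold lower, the second probe was below 0 in 7 and at least 2-fold lower in 2. The 8 spike-in controls well above background, meant to be added in equal amounts, had a median log2 difference of -0.01 and ranged from -0.13 to 1.20.

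**Figure D4:**
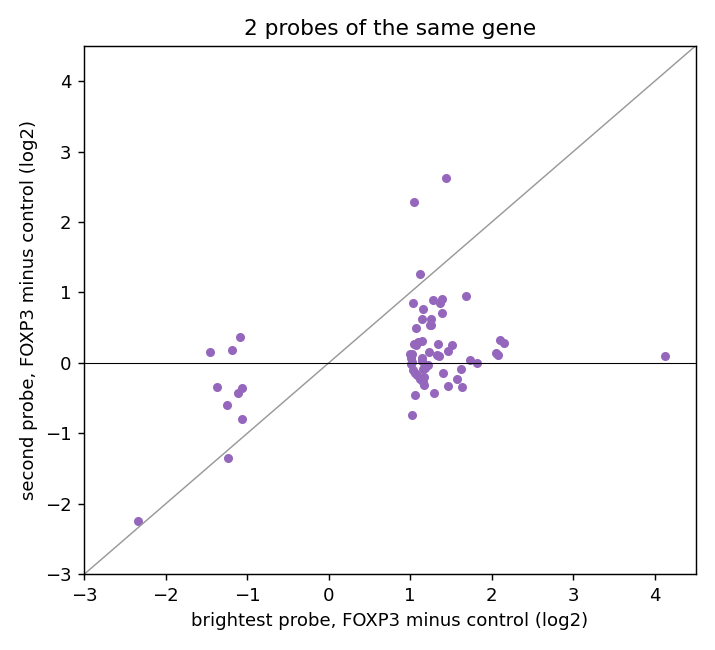
Log2 difference, FOXP3 minus control, of the second brightest probe against that of the brightest probe, for each gene with more than 1 detected probe whose brightest probe differed at least 2-fold. The line marks equal values; of the 57 genes on the right, 3 have a second probe at least 2-fold higher.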

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

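No paired analysis was possible because each group has 1 array. The settings with GC content and with protein-coding genes, and those for the agreement of probes, were chosen after the results were seen. The excess of higher over lower genes held under the alternatives tried, but the counts did not. From 231 higher and 23 lower genes, the counts became 94 and 10 with normexp, 101 and 10 without background subtraction, 60 and 9 among genes at or above the median signal, and 1008 and 263 with no background filter. They became 770 and 267 at 1.5-fold and 45 and 2 at 3-fold, which the fold size itself brings about. The lower genes were 35 with quantile normalization, 36 in the deposited value table, 15 with the mean over probes and 15 with probes of at most 60% GC. With the positive-and-significant flag, genes on 1 array only with a bound of at least 2-fold went from 80 to 391 on the FOXP3 array and from 8 to 146 on the control array. On the log2 scale the FOXP3 bound, 6.53, was 3.63 with normexp and 3.89 without background subtraction. The ARHGAP15 bound, 1.08, was 0.55 and 0.43 in those settings, 0.86 with quantile normalization, 0.86 in the deposited value table and 0.93 with cyclic loess, each under 2-fold. Lists below the random range went from 3 to 6 with cyclic loess and to 5 with the mean over probes. The probe correlation, 0.25, was 0.21 with quantile normalization, 0.22 with cyclic loess and 0.21 in the deposited value table. Ribosomal protein genes went from 0.29 to -0.059 with quantile normalization and to -0.059 in the deposited value table, where the median of all genes was -0.06, so the shift from the typical gene was lost. RPL14 reversed from 1.40 to -0.46 in both, where another probe became the brightest. Apart from RPL14, the amounts added to dim signals in the 2 background settings, and where a count or filter shows it, the cause was not tested. Extracellular matrix, G2/M, histone and metallothionein lists stayed past the random range, in the same direction, under all 13 alternatives, but the metallothionein median ran from 0.23 to 0.61 and the histone median from 0.16 to 0.25. Those 13 are not separate checks. Scaling to the median of detected probes or to the spike-ins shifts all genes alike, so it could not change a list's call. The deposited value table nearly repeats quantile normalization. The NRF2 call was lost among genes at or above the median signal, and the apoptosis call there and with the mean over probes.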

Other observations

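Every test below was chosen after its result was seen, except the tests of scaling, of 5′ against 3′ probes and of the members' second probes. For the second probes the measure and its bounds were fixed beforehand, but the rule that a random range holding the list's own median decides nothing was added after the percentiles were seen.

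Differences past 2-fold were more frequent for probes of high GC content. Of 211 detected probes above 70% GC, 16.1% were at least 2-fold higher and 3.32% at least 2-fold lower. In the 5 bins up to 60% GC, 1.31% to 2.43% were higher and at most 0.33% lower, and above 60% and up to 70% GC 6.58% were higher and 0.33% lower. Of 376 detected pseudogene probes, 8.51% were at least 2-fold higher, against 1.84% of 20560 probes of protein-coding genes. Most higher genes remained without either kind of probe. With probes of at most 60% GC, 191 genes in place of 231 were higher and 15 in place of 23 lower. Among protein-coding genes alone, 192 were higher and 22 lower. CRHR2, a receptor for stress peptides that was looked at after its values were seen, differed by 4.13 at 1 probe and by 0.10 at another.

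The first pattern weighed was the excess of higher over lower genes. Scaling is argued against, since the ratio, 10.04 in the main setting, was 4.89 or more under the 7 other background and scaling settings. In 57 genes with another detected probe, the other probes had a median log2 difference of 0.11 (bootstrap 95% interval over genes 0.03 to 0.27) against 1.22 for the brightest, which argues against higher transcript levels read alike by every probe as the whole cause. Whether slide differences at single probes made the excess, also judged on that 0.11, stays open. Genes were picked by the brightest probe, probes can read different transcripts, and slide and group cannot be told apart. The 8 detected spike-in controls, meant to be equal, ran from -0.13 to 1.20 on the log2 scale. The one at 1.20 had a spot SD of 0.236 on the control array and 0.145 on the FOXP3 array. Some control probes thus differed between the arrays beyond spot error, mostly upward in size, but how many genes did so is not known. A wider set took 190 genes with any probe at least 2-fold higher and another detected probe on the same strand. In these the 5′ probe was the higher in 63.7% (exact binomial 95% interval 56.4% to 70.5%). Across 5487 genes with a 5′ and a 3′ probe, the median log2 difference of the 5′ probe minus that of the 3′ probe was 0.08, far under 2-fold. A difference in RNA integrity or labelling may therefore contribute, but its typical size was small. Probe GC content had a Pearson r of 0.23 with the log2 difference across probes. The comparison of 5′ with 3′ probes took no account of it, so it cannot tell these sources apart. Genes with a single detected probe stay open, as does transfection with FOXP3 itself.

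The second pattern was CSH1, a placental hormone gene, chosen after its values were seen. Its 2 probes at the 3′ end (chromosome 17, 61972271 to 61972335 in hg19) were among the brightest on the control array, at 88414 and 92497, and read 16437 and 16067 on the FOXP3 array. A defect of single spots is argued against, as the probes' log2 differences lay 0.10 apart. A CSH1 probe farther 5′ differed by 0.20 but read 11.6 and 11.7, near the floor, another was not well above background on either array, and the detected probes of the related CSH2 and GH2 were 0.61 to 1.07 higher. Thus a growth hormone family 3′ end carried by the plasmids, a candidate explanation, and a lower CSH1 transcript level, at the same 0.20, cannot be told apart. The vector sequences were not used here.

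The third pattern was the 8 lists past the random range. Probe GC content as the whole cause is argued against for 7 of them, whose percentiles among lists matched on signal and GC were 0.01 for extracellular matrix, 98.7 for apoptosis, 0.01 for G2/M, 99.8 for histones, 99.5 for NRF2, 100.0 for metallothionein and 99.99 for ribosomal protein genes. For hypoxia genes it was 2.81, with the same median of -0.09 and a random range of -0.10 to 0.08 in place of -0.08 to 0.12, so the call ended because the range moved. Differences of single probes are argued against for ribosomal protein genes, whose second probes lay at percentile 99.3 in the main scaling. The second probes lay at percentiles 83.9 for apoptosis, 19.2 for G2/M, 62.6 for histones and 57.5 for hypoxia genes, between 10 and 90, as was written beforehand for differences of single probes. That explanation is left open for them and not favoured, since by the later rule the random ranges, over 8 to 19 members, were wide enough to hold each list's own median. It is also open at 2.71 for matrix, 4.26 for NRF2 and 96.7 for metallothionein genes. The second probes of NRF2 genes had a median of -0.08, opposite in sign to the list's 0.17. FOXP3 transfection and the slide cannot be told apart as sources of these shifts.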
